A study of Homo sapiens with 8 samples.

How the data were processed

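Total RNA of the 6 cultures was extracted with Trizol, and biotinylated cRNA was made for Illumina arrays, per the labels' protocols. The values deposited by the authors came as 2 tables. The first holds, per the file headers, a signal intensity and a detection p-value for each of the 8 arrays, with no normalization between arrays; the software behind it is not given in the sources used here. Its rows are genes and not probes: of 31412 rows with a name and values, 24130 have detection p-values that are whole multiples of 1 part in 770 on every array (within 0.002 of a whole number), as a single probe would have when ranked among 770 negative controls, and 7282 do not and were taken to combine several probes. A further 3266 blank rows were left out. The second table, of 31405 rows, holds intensities that the authors normalized between arrays on the linear scale by a method not given in the sources used here. Its columns have medians of 70.96 to 72.73, and each followed the same array of the first table most closely. Names in the form of dates stand on 27 rows of the first table and were kept.

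Cultures were assigned from the sample titles. A repeat array is a second RNA sample of a culture, and the series text states that the values of both samples were averaged. The title of the vehicle repeat names culture 3 and that of the estradiol repeat names culture 1, whereas the series text says that replicate 3 of each treatment was repeated. The titles were followed, and averaging the estradiol repeat with culture 3 was an alternative. The arrays lay on 2 chips, per the labels: chip A held 2 vehicle arrays (cultures 1 and 3 repeat) and 1 estradiol array (culture 1), and chip B held 2 vehicle and 3 estradiol arrays.

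All steps below started from the first table and used R 4.3.3 with limma 3.58.1. Signals were background-corrected with the normexp model, the mean and SD of the negative controls being inferred from the detection p-values of the single-probe rows. That gave a background mean of 59.2 to 65.5 and an SD of 7.61 to 11.6 per array. Inference from all rows, the default of limma, gave an SD of 292 to 397, because the detection p of a combined row is not a rank of its signal, and was kept as an alternative chosen after the data were examined. An offset of 16 was added, the values were quantile normalized and log2 transformed, and the arrays of a culture were averaged. The offset shrinks the fold change of dim genes. A row was tested where its detection p was under 0.01 on at least 3 of the 8 arrays, which left 11191 rows and set aside 20221. The filter also removed bright combined rows: 1192 rows set aside reached the level of the lowest detected single-probe row on at least 3 arrays. All were combined rows by construction, since a single-probe row at that level is itself detected.

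Estradiol and vehicle were compared over 3 and 3 cultures with lmFit and eBayes (limma), without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are differences of mean log2 values. A gene detected on no array of a treatment is given as at least N-fold: the brighter mean was set against the mean over arrays of the higher of its own value and the lowest detected single-probe value. A combined row need not share that floor, so the bounds of CXCR7, KRT16 and LYZ, which are combined rows, are nominal. Named genes followed a rule fixed before the data were examined: the 12 largest rises and 12 largest falls among called rows without overlap of the groups, ESR2, each detected cystatin, and up to 4 members of each list with the smallest p; other list members named were chosen after their values were seen. Of the genes this rule takes, 1 of the largest rises and 1 list member are not reported here. The 26 lists were also fixed beforehand. Of their 676 entries 675 matched a row, older symbols being updated through the gene table of the GRCh38.p14 assembly, in which 17757 row names were current symbols, 3283 had 1 current symbol as a synonym and 10372 did not match. The unmatched entry was CDK1. Lists with at least 5 tested members (25) were tested with camera at an inter-gene correlation of 0.01, again with an estimated correlation, and with fry. The plan had assumed several probes per gene and a rule to choose among them, which gene rows made unnecessary.

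The fit was tested on simulated data with 200 of 11191 rows changed in the comparison of estradiol with vehicle. It recovered 26.9% of rows changed by a log2 of 0.5, 92.5% at 1 and 100% at 2, with 7 false calls among 153. The simulated errors were independent between rows, and far fewer rows were changed than the 27.7% called in the data. These rates may therefore not carry over. Alternatives covered the culture of the repeat array, the use of repeats, the replicate number and the chip as blocks, each chip alone, background correction, normalization, the detection filter, the variance model, array weights and each culture left out; 3 more were added after the data were examined, namely leaving out the vehicle 3 repeat array, inferring the background from all rows, and filtering on signal in place of detection p. Probe sequences were not used here.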

Results

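Transcript levels were measured on Illumina bead arrays in MDA-MB-231 cells, a triple-negative breast cancer line, engineered to express oestrogen receptor beta (ERβ, the product of ESR2) when given doxycycline. Every culture received 100 ng/ml doxycycline and was then kept for 5 days with the ethanol vehicle or with 1 nM estradiol, the natural ligand of the receptor. There were 3 cultures per treatment. A second RNA sample of 1 culture per treatment was hybridised as well, which gave 8 arrays, and the 2 arrays of such a culture were averaged so that each culture counted once. Between 10172 and 11123 of the 31412 gene rows were detected per array, with a median raw signal of 66.3 to 75.4. The number of arrays limits the precision of every value. Where no separate dish, passage or day is stated for a replicate, the p-values measure only the spread between these cultures.

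Before any test, the arrays separated by treatment. The first principal component held 61.9% of the variance and placed all 4 vehicle arrays between -32.4 and -22.2 and all 4 estradiol arrays between 25.4 and 26.4. Arrays of different estradiol cultures correlated across genes at r = 0.990 to 0.997, arrays of different vehicle cultures at 0.985 to 0.992, and arrays of different treatments at 0.960 to 0.973. The repeat array of vehicle culture 3 stood apart from the others on the second component, which held 13.3% of the variance, at -25.7 against 19.8 for the first array of that culture. These 2 arrays of a single culture correlated at 0.980, below every pair of different vehicle cultures. The 2 arrays of estradiol culture 1 correlated at 0.992, as the repeat did with culture 3, against 0.997 between estradiol cultures 2 and 3. In neither repeated culture were its 2 arrays the closest pair of the treatment.

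**Figure D1:**
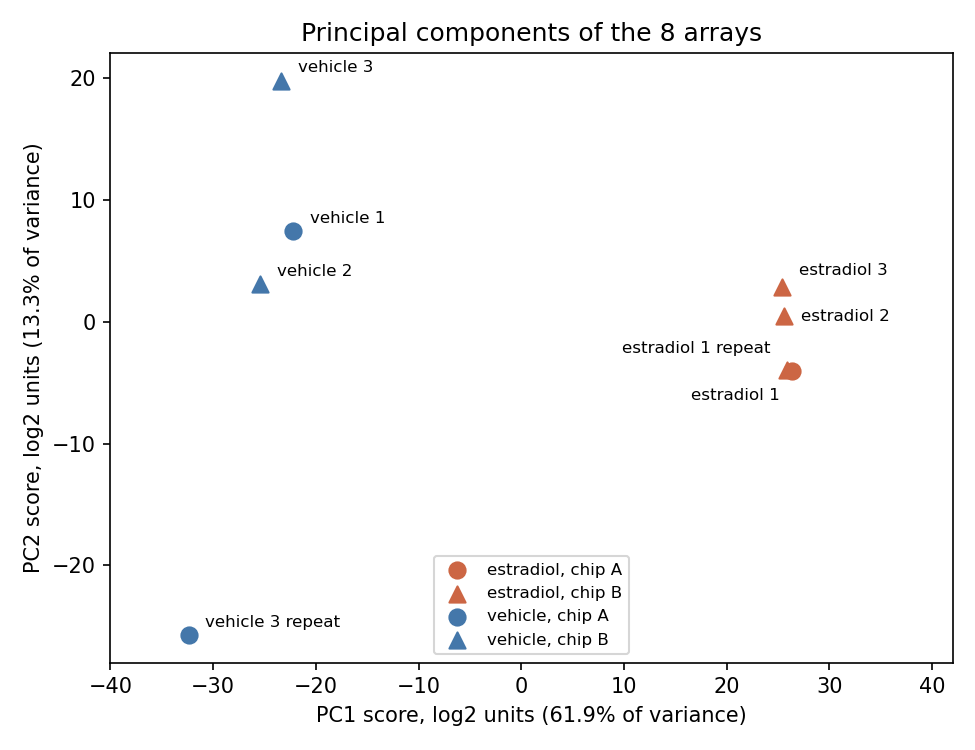
Scores of the 8 arrays on the first (horizontal axis, 61.9% of variance) and second (vertical axis, 13.3%) principal components of the log2 values of 11191 gene rows, coloured by treatment, with circles for chip A and triangles for chip B. The estradiol arrays lie at 25.4 to 26.4 on the first component and the vehicle arrays at -32.4 to -22.2, and the vehicle 3 repeat array lies at -25.7 on the second.

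The comparison of estradiol with vehicle asked which transcripts respond to the ligand once ERβ is present. No culture went without doxycycline, so changes that need ERβ cannot be told from other effects of estradiol. With estradiol CST5, which encodes the secreted cysteine protease inhibitor cystatin D, rose 93.0-fold (log2 change 6.54, SE 0.108, adjusted p = 5.88e-11). This size depended on the background correction, and the log2 change was 5.30 without it and 4.31 to 6.67 over the alternatives. KRT13, a keratin of stratified epithelia, went from not detected on any vehicle array to at least 49.5-fold higher. In the other direction, the inflammatory cytokine genes IL1A, IL1B and IL6 fell (log2 changes of -3.29, -3.09 and -2.50). LCN2, which encodes the iron-siderophore carrier lipocalin 2, fell by 3.52. Interferon-stimulated genes and oestrogen-response genes rose as groups, and genes of mitosis fell. Of 11191 gene rows tested, 1518 were higher and 1586 lower with estradiol at an adjusted p under 0.05 (limma), which was 27.7% of the rows tested. The larger changes were mostly rises: 318 rows rose and 142 fell at least 2-fold, and 55 rose and 19 fell at least 4-fold. These counts rest on fitted values, and 17 of the 55 and 0 of the 19 were not detected in a treatment group. At least 4-fold, 32 rose and 10 fell without background correction, 33 and 10 in the values the authors normalized, and 26 and 7 with the background inferred from all rows. In 3060 of the 3104 called rows the 3 vehicle and 3 estradiol values did not overlap. This held for 42.8% of all rows tested, against 10% by chance. The split between rises and falls depended on scaling. As an alternative to quantile normalization, each array was centred on its median over all 31412 rows, most of them not detected. This centring moved the median change of the tested rows from -0.0232 to 0.143 (log2). It called 2052 rows higher and 540 lower, so that 79.2% of calls were rises in place of 48.9%. With the chip as a block 2382 rows were higher and 2690 lower, in a fit that gave the repeat arrays more weight than independent ones. Within chip A alone, where 1 estradiol array was assumed to vary like the 2 vehicle arrays, 553 were higher and 401 lower, and within chip B alone, with 5 arrays, 1025 and 880. Without vehicle culture 3, estradiol culture 2 or estradiol culture 3, the rows lower with estradiol numbered 921, 1010 and 950.

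The other genes with the largest rises included PADI4, which encodes a peptidylarginine deiminase that converts arginine to citrulline in histones and other proteins (log2 change 4.89, SE 0.164), and OLFML3 (at least 17.8-fold). With them rose the semaphorin gene SEMA3B (4.55, SE 0.125), whose vehicle mean of 4.93 lay under the lowest detected single-probe level of 5.14 to 5.39, and CXCR7, now named ACKR3, an atypical chemokine receptor (at least 11.8-fold). The lysyl oxidase gene LOXL4 rose by 3.94 (SE 0.104), the chemokine gene CXCL14 at least 8.62-fold, and KRT17 by 3.71 (SE 0.158). Among the genes with the largest falls were the collagenase gene MMP1 (log2 change -2.95, SE 0.214) and the cytokine genes IL24 (-2.90, SE 0.104) and IL11 (-2.46, SE 0.110). They further included the chemokine gene CXCL2 (-2.45, SE 0.135) and G0S2, an inhibitor of adipose triglyceride lipase (-2.81, SE 0.149). ALOX5AP, which leukotriene synthesis requires, was at -2.58 (SE 0.117), and the acute phase genes were at -2.57 for SAA1 (SE 0.111) and -2.52 for SAA2 (SE 0.235). The 24 rows with the largest rises and falls all had an adjusted p of at most 2.78e-05 (limma). All 24 also passed with the chip as a block and within chip B. In these fits and within chip A, with its 1 estradiol array, the log2 change was 0.902 to 1.15 times that given here. The sizes and bounds hold for the background correction used: the fold moved by over 1.5 times for 14 of the 24 without correction, for 13 in the values the authors normalized, and for 18 with the background inferred from all rows. Under the last of these the log2 change was 1.15 for OLFML3, 1.17 for SEMA3B, 0.71 for CXCR7, 0.50 for CXCL14, -1.62 for IL24, -0.25 for IL11, -0.38 for G0S2, -0.37 for ALOX5AP and -0.46 for SAA2. Of the 4 vehicle arrays, 3 detected CST2 and 1 detected SEMA3B, and of the 4 estradiol arrays, 2 detected IL11 and 3 each G0S2 and SAA2. SAA1 and SAA2 are near-identical in sequence, as are several cystatins, and probe sequences were not used here, so signal shared between such paralogs cannot be set aside.

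**Figure D2:**
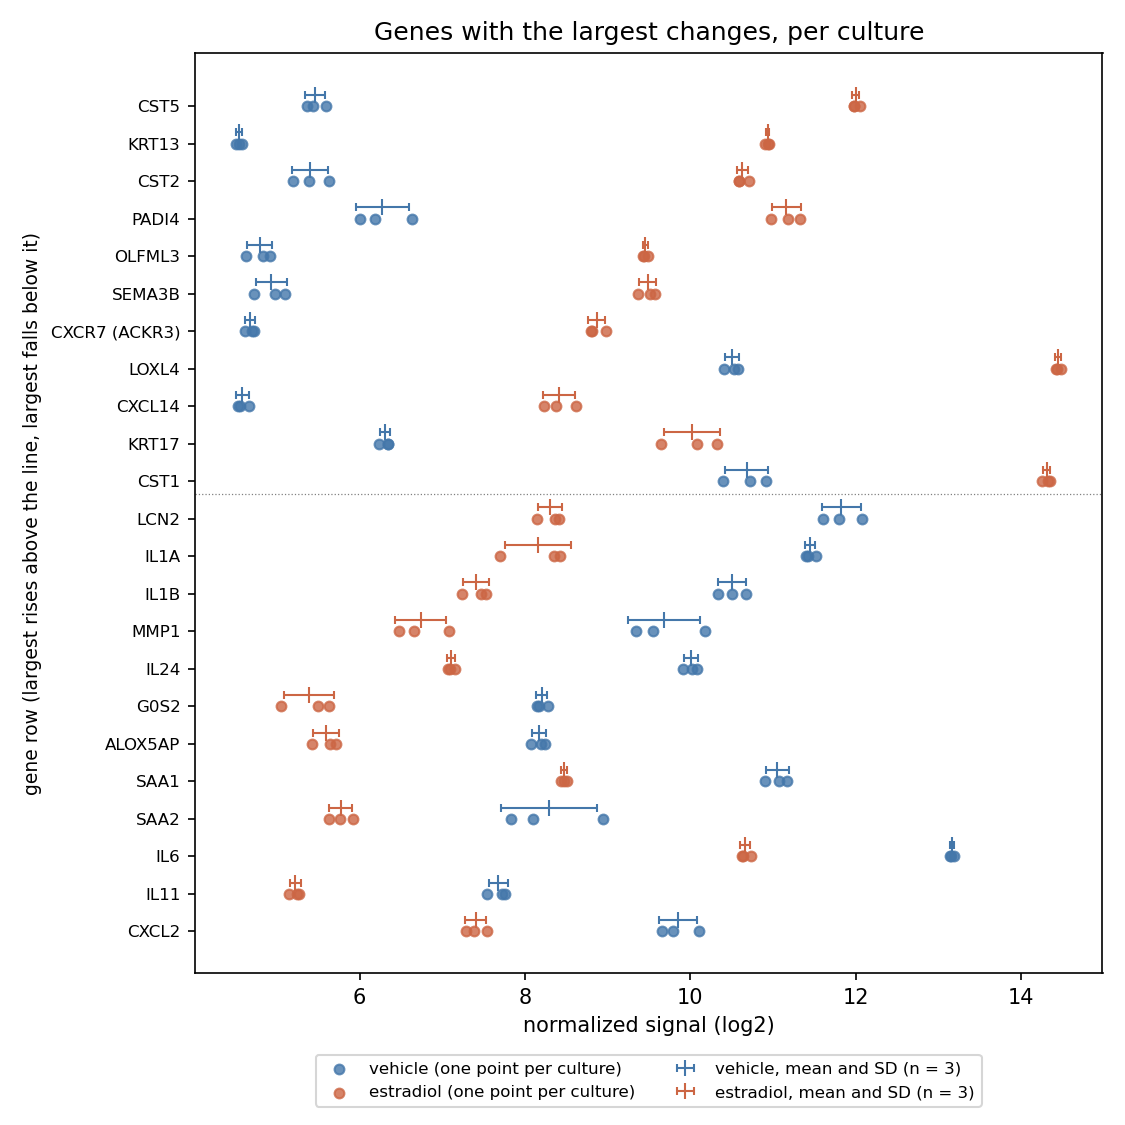
Normalized log2 signal (horizontal axis) of 11 of the 12 gene rows with the largest rises and the 12 with the largest falls (vertical axis), with a point for each of the 3 vehicle and 3 estradiol cultures and, above the points, the mean and SD of each group (n = 3). The groups do not overlap for any of these rows, such as CST2 (mean 5.40 in vehicle and 10.63 with estradiol) and CXCL2 (9.85 and 7.40).

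ESR2 itself was detected on all 8 arrays and was lower with estradiol, at a mean log2 signal of 10.17 against 11.34 in vehicle (log2 change -1.17, SE 0.118, adjusted p = 4.97e-05, limma). Within chip A alone the change was -1.34, within chip B alone -0.99, and with the chip as a block -1.15. Whether this row measures the introduced gene, the cell's own or both was not checked, since probe sequences were not used here.

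The cystatins, inhibitors of cysteine proteases, were followed up by the study from these samples, so that their direction is not independent evidence here. Of the 7 detected members 5 rose, 1 fell and 1 did not pass, with the same counts when adjusted over the list alone, which is likewise not independent evidence. Beside CST5, the type 2 cystatin genes CST2 (log2 change 5.22, SE 0.128), CST1 (3.63, SE 0.137) and CST4 (3.15, SE 0.111) rose most. CST3 rose by 0.75 (SE 0.149), CST7 fell by 0.70 (SE 0.146), and CSTB was at 0.17 (adjusted p = 0.285, limma). CST6, CST8, CST9, CST11 and CSTA were not detected on any array. As a list the cystatins rose. Camera gave adjusted p = 2.49e-06 for the list, and adjusted p = 0.115 with an estimated correlation. The vehicle 3 repeat array lay below the first array of its culture for this list, by a median of -0.279, and 5 members rose and 1 fell without it.

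Genes known to respond to oestrogen through ERα in breast cancer cells rose as a group where tested. Of 19 tested members 13 rose, 1 fell and 5 did not pass, with the same counts adjusted over the list alone. For the list as a whole, camera gave adjusted p = 2.69e-09 (adjusted p = 0.03 with an estimated correlation). Besides KRT13, they included CTSD, which encodes the lysosomal protease cathepsin D (log2 change 2.68), IGFBP4, an IGF-binding protein gene (2.67), HSPB8 (2.54), and WISP2, now CCN5 (at least 3.31-fold). TFF1, a widely used marker of ERα activity, rose from below detection to at least 1.09-fold higher. Members such as XBP1 (0.06), CA12 (-0.05) and NRIP1 (0.13) did not pass. MYC fell by 0.43. The list holds 32 genes, and those the detection filter set aside, among them PGR, AREG, STC2, GREB1 and TFF3, are in none of these counts.

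Interferon-stimulated genes rose together. Of 33 members 24 rose, 1 fell and 8 did not pass over all genes, and 26 rose and 1 fell when adjusted over the list alone (camera adjusted p = 4.43e-15; adjusted p = 0.0173 with an estimated correlation), with a median log2 change of 1.05. The rises included the exonuclease gene ISG20 (2.18), the antiviral GTPase genes MX1 (2.09) and MX2 (1.76), and the ubiquitin-like modifier gene ISG15 (1.72). The immunoproteasome gene PSMB8 fell by 0.54. In the same cultures, NF-kB and cytokine genes fell as a list, with 11 of 21 members lower, 3 higher and 7 not passing, and the same counts adjusted over the list alone. The shift of the list had a camera adjusted p = 0.00166, or adjusted p = 0.0744 with an estimated correlation. With IL1A, IL1B, IL6 and CXCL2, the members that fell included the cytokine genes IL8, now CXCL8 (-2.34), and CSF2 (-1.64). The feedback inhibitor genes NFKBIA (-0.06) and TNFAIP3 (0.18) did not pass. The members that rose were BIRC3, an inhibitor of apoptosis (1.48), and the cytokine genes IL32 (0.72) and CCL5 (0.63).

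Genes of the cell division cycle fell. Of 34 mitosis genes 0 rose, 29 fell and 5 did not pass, with 31 lower when adjusted over the list alone (camera adjusted p = 1.32e-14; adjusted p = 0.0485 with an estimated correlation), and the median log2 change was -0.78. They included the kinesin gene KIF2C (-1.24), the kinase gene AURKB (-0.99), CCNA2, which encodes cyclin A2 (-0.91), and KIF23 (-0.83). Of 29 DNA replication genes 0 rose, 17 fell and 12 did not pass, with 21 lower when adjusted over the list alone. By camera the list shifted at adjusted p = 6.11e-07, against adjusted p = 0.132 with an estimated correlation. They included RRM2, a ribonucleotide reductase subunit gene (-0.78), the primase gene PRIM1 (-0.78) and GINS2 (-0.73). The vehicle 3 repeat array was higher than the first array of its culture for this list, by a median of 0.272 (log2), and 15 members fell without that array.

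Epithelial and mesenchymal genes both rose as lists where tested. The detection filter left 17 of 30 epithelial and 11 of 29 mesenchymal genes listed. Those it set aside, among them OCLN, GRHL2, ZEB1, SNAI1 and TWIST1, are in none of these counts. Of 17 epithelial genes 11 rose, 1 fell and 5 did not pass, with 12 higher adjusted over the list alone. Camera gave adjusted p = 8.46e-07 for the list, and adjusted p = 0.0895 with an estimated correlation. CDH1, which encodes E-cadherin, went from undetected in vehicle to at least 4.71-fold higher, the transcription factor gene ELF3 rose by 2.24 and JUP, which encodes plakoglobin, by 1.92, while the tight junction gene CLDN1 fell by 1.12. Of 11 mesenchymal genes 7 rose, 1 fell and 3 did not pass, with the same counts adjusted over the list alone. Camera gave the list adjusted p = 3.06e-05, or adjusted p = 0.0556 with an estimated correlation. Those that rose included S100A4 (1.95), the collagen genes COL6A1 (1.81) and COL1A2 (1.60), and FN1, which encodes fibronectin (1.43). The FN1 vehicle mean of 5.25 lay at the lowest detected single-probe level, and its change was 0.09 with the background inferred from all rows. Basal and myoepithelial markers also rose, with 5 of 8 higher, 2 lower and 1 not passing, and the same counts adjusted over the list alone (camera adjusted p = 0.000617; adjusted p = 0.0744 with an estimated correlation): with KRT17, the integrin gene ITGB4 rose by 2.18 and KRT16 at least 1.66-fold. The luminal markers did not shift as a list (camera adjusted p = 0.321). Of 7 tested, 2 were higher (KRT8, 1.63, and TFF1), 2 lower (GATA3, -0.45, and MLPH, -0.39) and 3 not passing. Adjusted over the list alone 3 were higher. The detection filter left 8 of 14 basal and 7 of 16 luminal genes listed. It set aside KRT5, KRT6A, KRT6B, KRT14 and TP63 among the first, and ESR1, FOXA1 and PGR among the second.

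TGF-beta target genes rose as a list (camera adjusted p = 0.0206; adjusted p = 0.139 with an estimated correlation), but members went in both directions, with 12 of 26 higher, 5 lower and 9 not passing, and the same counts adjusted over the list alone. The collagen gene COL5A1 rose by 1.62 and ID3 by 1.36, while IL11 fell by 2.46. The list was not past the threshold when each array was centred on its median (camera adjusted p = 0.0575, within a range of 0.000573 to 0.0575 over the alternatives). Among the ligands, receptors and SMADs of the TGF-beta and BMP pathways, 4 of 14 rose, 3 fell and 7 did not pass, with the same counts adjusted over the list alone and no shift of the list (camera adjusted p = 0.251). The inhibin beta B gene INHBB rose at least 7.88-fold and TGFBR3, which encodes the co-receptor betaglycan, by 2.16. The ligand gene TGFB2 (-1.56), SMAD3 (-1.14) and FST, which encodes the activin antagonist follistatin (-1.60), fell.

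Matrix proteases and their inhibitors went both ways, with 9 of 25 higher, 6 lower and 10 not passing, and 13 higher and 7 lower adjusted over the list alone. The median log2 change was 0.295 and the mean -0.0583, and camera found no shift (adjusted p = 0.272). With MMP1, the stromelysin gene MMP3 fell by 1.96 and SERPINB2 fell by 1.78, each detected on 1 of 4 estradiol arrays. Their estradiol means of 5.18 and 4.80 lay at or under the lowest detected single-probe level, and with the background inferred from all rows the changes were -0.15 and -0.10. PLAT, the tissue plasminogen activator gene, rose by 1.37.

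Unfolded protein response genes fell as a list, with 12 of 26 lower, 1 higher and 13 not passing, and 13 lower adjusted over the list alone. For the list as a whole, camera gave adjusted p = 5.08e-05 (adjusted p = 0.0556 with an estimated correlation). The members that fell included DDIT3 (-2.14), TRIB3 (-1.46), SLC7A11, the cystine transporter gene (-1.36), PPP1R15A (-1.03) and the chaperone gene HSPA5 (-0.96), while CHAC1 (-0.12) and PHGDH (-0.33) did not pass. The vehicle 3 repeat array lay above the first array of its culture for this list by a median of 0.280, and 10 members fell and 0 rose without it. Metallothionein genes, which encode metal-binding proteins, were lower for 5 of 6 members with 1 not passing, also adjusted over the list alone (camera adjusted p = 0.000556; adjusted p = 0.189 with an estimated correlation), among them MT1G (-1.51), MT1E (-1.09) and MT2A (-0.88). Here the vehicle 3 repeat array lay below the first array by a median of -0.471, 5 of 6 fell without it, and the close sequence similarity of these genes again leaves shared signal open.

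Cholesterol synthesis genes rose by small amounts, with 7 of 23 higher, 1 lower and 15 not passing, also adjusted over the list alone. The shift of the list had a camera adjusted p = 0.00388, or adjusted p = 0.101 with an estimated correlation. The sterol reductase gene TM7SF2 rose by 1.51 and the others that rose by 0.46 to 0.53, and INSIG1, which restrains the pathway, fell by 0.51. The list was past the threshold in 23 of 24 alternatives. The exception was chip A alone, with 1 estradiol array, where the median log2 change was 0.194. Immediate early genes rose as a list with 6 of 21 higher, 3 lower and 12 not passing, and 10 higher adjusted over the list alone (camera adjusted p = 0.00896; adjusted p = 0.139 with an estimated correlation), led by KLF4 (1.40) and by ZFP36, which encodes an mRNA-destabilising protein (1.21). Hypoxia and glycolysis genes were higher for 8 of 25 members, lower for 1 and not passing for 16, with 8 higher and 2 lower adjusted over the list alone. By camera the list shifted at adjusted p = 0.0298, against adjusted p = 0.131 with an estimated correlation. They included PFKFB3 (0.79) and the glucose transporter gene SLC2A3 (0.80), and the list was past the threshold in 19 of 24 alternatives, with adjusted p from 0.000171 to 0.164.

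The remaining lists did not pass. Ribosomal protein genes had 1 of 29 members lower (RPL4, -0.62), 0 higher and 28 not passing, with the same counts adjusted over the list alone (camera adjusted p = 0.0567), and the list was past the threshold in 13 of 24 alternatives, with adjusted p from 0.00224 to 0.164. Oxidative phosphorylation genes had 1 of 30 higher (NDUFA4, 0.55) and 29 not passing (camera adjusted p = 0.364). Of 17 fatty acid and lipid storage genes 2 rose, 1 fell and 14 did not pass (0.514); the lipid droplet gene PLIN2 fell by 1.18 and ACSS2 rose by 0.82. Of 15 p53 targets 2 rose, 2 fell and 11 did not pass (0.439), with 4 higher and 2 lower adjusted over the list alone, among them XPC (0.93). Of 16 NRF2 targets 2 rose, 4 fell and 10 did not pass (0.598), with the aldo-keto reductase gene AKR1C3 at 1.58 and TXNRD1 at -0.72. Of 16 nuclear receptors and coregulators 4 rose, 2 fell and 10 did not pass (0.591), among them ESR2 and EZH2 (-0.50). As markers of other cell types, 3 of 5 blood cell markers rose, 0 fell and 2 did not pass (camera adjusted p = 0.0982), with 1 lower as well adjusted over the list alone: CD34 rose by 1.31, LYZ at least 1.17-fold and CD68 by 0.41. Only 2 fibroblast markers were detected, COL1A2, which rose, and PDGFRB, which fell by 0.48, too few for a test of the list. Counts adjusted over the list alone were the same as over all genes for the oxidative phosphorylation, fatty acid, NRF2, nuclear receptor and fibroblast lists.

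In all, 15 of the 25 lists tested were past the threshold with the preset correlation of 0.01, 10 upward and 5 downward. With an estimated correlation 3 held, those of interferon-stimulated, oestrogen-response and mitosis genes. Camera with an estimated correlation takes its degrees of freedom from the 6 cultures, which makes it stricter. The estimate was -0.074 for mesenchymal genes and -0.043 for basal markers, below 0.01, and 0.37 for cystatins. Correlation among members thus does not account for the loss in every list. Of the members named, MX2 and ITGB4 were detected on 3 of 4 vehicle arrays, and ELF3, CD34, CA12 and ACSS2 on 2. With estradiol TFF1, ITGB4, CA12 and MT1E were detected on 3 of 4 arrays, ACSS2 and CLDN1 on 2 and CD34 on 1. The rows of MT1E, ACSS2, CD34 and ITGB4 are combined rows, whose detection p is not a rank of their signal. Their estradiol means were 11.68, 10.46, 7.71 and 7.80. Other combined rows named include CXCR7, SEMA3B, IL24, FN1, SERPINB2, KRT16 and LYZ. The bounds of CXCR7, KRT16 and LYZ rest on a floor from single-probe rows that need not be theirs. Among the members named as changed, alternatives ended the call of INSIG1 in 10 of 24, of MLPH in 8, of CD68 and PDGFRB in 7 each, of GATA3, NDUFA4 and EZH2 in 4 each and of MYC in 3. The call was lost in 2 alternatives each for CST7, MT1G, PRIM1, RPL4 and PSMB8, and in 1 each for CST3, GINS2, SLC2A3, TFF1, BIRC3 and CCL5. The limit on sizes and bounds holds for list members too: of 132 called genes examined, the fold of 61 moved by over 1.5 times with the background inferred from all rows, of 27 without correction and of 21 in the values the authors normalized. With the background from all rows the log2 change was 0.43 for INHBB, 0.24 for CDH1, 0.17 for WISP2, 0.07 for KRT16, 0.04 for TFF1 and 0.04 for LYZ. By fry, which asks whether the genes of a list move on balance in a single direction, 21 lists passed. With the chip as a block and within chip B 16 lists were past the threshold. The median log2 change of interferon-stimulated genes was 1.02 with the chip as a block, 1.07 within chip B and 1.08 within chip A. In the same order, the median of mitosis genes was -0.74, -0.82 and -0.77, and that of oestrogen-response genes 0.668, 0.717 and 0.692. None of the 15 lists had a median of opposite sign when arrays were centred on their medians. With the preset correlation another division of the 6 cultures into 3 and 3 also put 11 lists past the threshold, while it called 0 single rows. Every other division mixes the treatments unequally, so it keeps part of the treatment difference, and the rest widens its spread. These counts are therefore no rate of false calls.

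**Figure D3:**
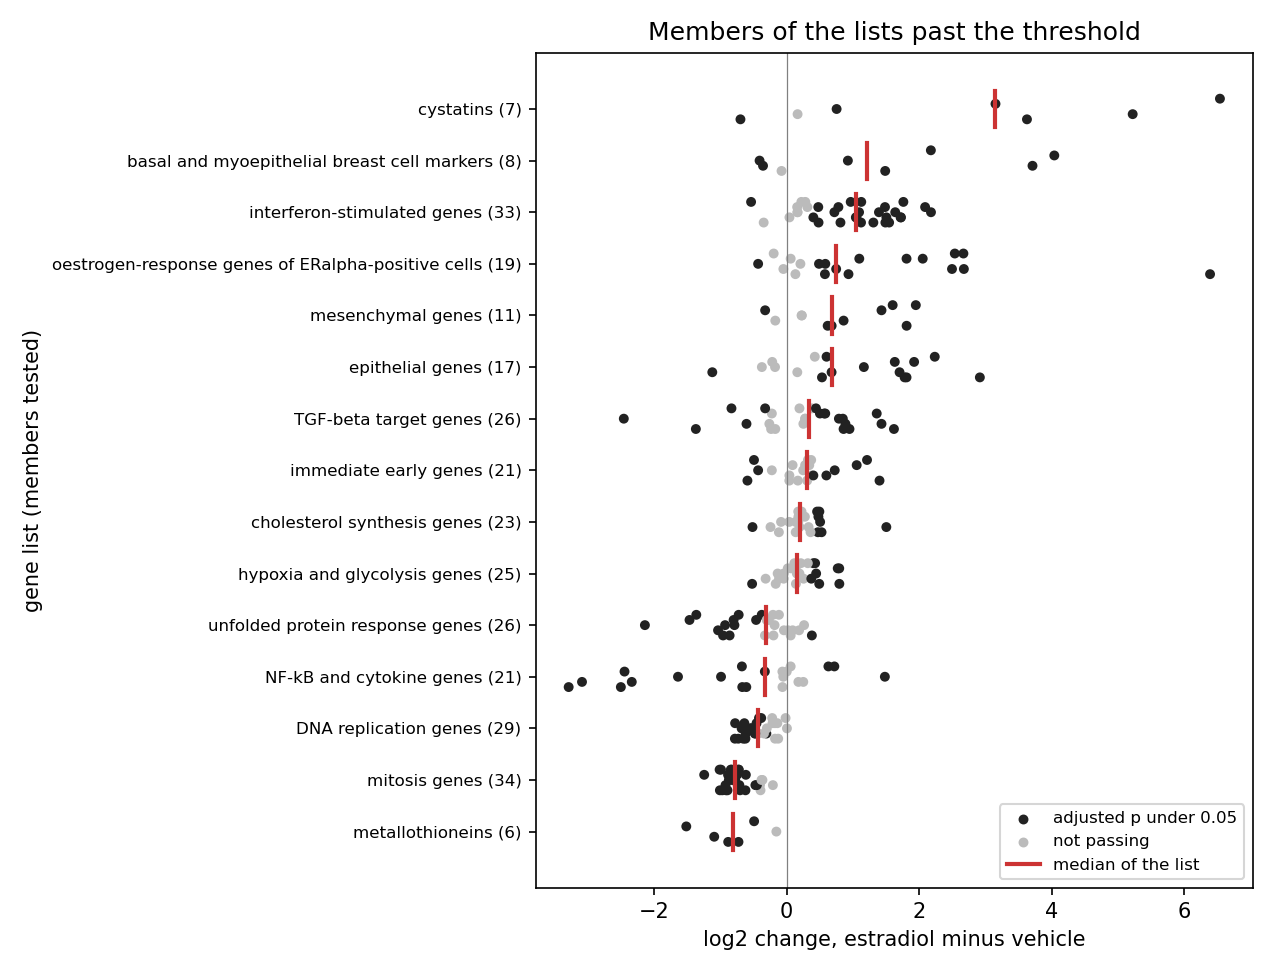
Log2 change with estradiol (horizontal axis) of each tested member of the 15 lists past the threshold (vertical axis, members tested in brackets), dark where the adjusted p was under 0.05 and grey otherwise, with a red bar at the median of the list. Medians run from 3.15 for cystatins to -0.803 for metallothioneins.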

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

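Leaving out the vehicle 3 repeat array, inferring the background from all rows and filtering on signal were chosen after the data were examined. Of the rows tested, no gene named as changed and no list past the threshold changed direction under any of the 24 alternatives; the fatty acid and nuclear receptor lists, which did not pass, changed direction in 1 each, and of the genes given as not passing CA12, CHAC1, NFKBIA and NRIP1 changed sign in 5, 5, 7 and 4. Calls were more often lower than higher (1586 and 1518), but more often higher in 10 of the alternatives. Of 2731 values of the 115 named genes under them, 2577 stayed on their side of the threshold, 105 lost a call and 49 gained one. Of 106 named genes called, 77 were called in every alternative run, the 24 largest rises and falls among them, and chip A alone lost the most calls (27). Against 1518 rows higher, 1586 lower and 15 lists, counts moved by over 1.5 times as follows. Fitting all 8 arrays with the culture as a random block gave 2412 lower, and adding the chip as a block 2382 higher and 2690 lower. The estimated correlation between arrays of a culture was -0.5 and -0.57 in these fits, set by the 2 repeated cultures. A negative value counts the arrays of such a culture for more than independent arrays, so the larger counts are not firmer evidence. Array weights gave 3080 higher and 3426 lower. Chip A alone gave 553 and 401 and chip B alone 880 lower, with fewer arrays in each. Centring arrays on their medians gave 540 lower; the cause was not tested. Estimating the inter-gene correlation left 3 lists. Leaving out each culture in turn gave 1034 to 1689 rows higher, 921 to 1698 lower and 14 to 16 lists; the lower count moved by over 1.5 times without vehicle 3 (921), estradiol 2 (1010) or estradiol 3 (950). The replicate block gave 1592 higher, 1676 lower and 15 lists, but same-numbered cultures deviated together by r = 0.13, 0.13 and -0.033, so the numbers were not taken to pair cultures. Without the vehicle 3 repeat array 1349 rows were higher and 1302 lower, with 16 lists. With the estradiol repeat averaged into culture 3, as the series text has it, 1428 and 1486 were called and 2787 calls were shared. Signal over background limits the dim genes: TFF1 ranged from 0.04 to 1.32 (log2) over the alternatives, and KRT13 was at 3.07 at its lowest. Averaging all probes of a gene was not run, since the rows are genes already.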

Other observations

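The families of gene rows, the runs of neighbours and the rows below the filter described here were looked at only after the results were seen, and so were the tests on the vehicle 3 repeat array and of ESR2 by chip. Of 143 families of at least 8 tested rows that share a symbol stem, 9 were past the threshold by camera (limma), and 0 with an estimated correlation (adjusted p = 0.631 for each of the 9), so that members of a family moving together by chance stays open. Histone rows rose, with 9 of 15 higher, 1 lower and 5 not passing (camera adjusted p = 0.000433): HIST1H2AC rose by 1.61 and the linker histone gene HIST1H1C by 1.00, although the vehicle 3 repeat array lay below the first array of its culture by a median of -0.426 for these rows. Rows with the stem S100, most of them genes of a family of calcium-binding proteins, were higher for 8 of 11 with 0 lower and 3 not passing (0.000569), among them S100A3 (1.90) and S100A11 (0.81). The 11 include S100PBP, which shares only the stem and did not pass (0.10). Semaphorins were higher for 6 of 11 rows, lower for 1 and not passing for 4 (0.00753), with SEMA4F (0.78) beside SEMA3B and with SEMA7A at -0.68. Keratin rows, which include pseudogenes of close sequence, were higher for 10 of 18, lower for 2 and not passing for 6 (0.000266), with KRT15 at 1.60. The IFI rows overlap the interferon list (5 of 8 higher, 0 lower, 3 not passing, 0.00304).

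Of the families lower by camera, the RNA exosome family EXOSC was lower for 8 of 10 rows with 2 not passing (camera adjusted p = 0.00753), led by EXOSC5 (-0.86), and the ribosomal RNA processing family RRP for 5 of 8 with 3 not passing (0.0237), led by RRP9 (-0.83). Most small nucleolar RNA rows did not pass: 14 of 37 SNORA rows were lower, 1 higher and 22 not passing (0.00153), and 8 of 25 SNORD rows were lower, 0 higher and 17 not passing (0.0211), with SNORA10 at -1.24 and SNORD96A at -1.17. The calls of S100A11, SEMA7A, EXOSC5, RRP9 and SNORA10 were each lost in 1 of 24 alternatives. These families keep the sign of their medians when arrays are centred on their medians. The vehicle 3 repeat array lay below the first array by a median of -0.288 for SNORD rows and -0.0526 for SNORA rows.

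The detection filter set aside 418 rows that a fit without it called, 241 higher and 177 lower. Of these, GSN (2.40) and PODXL (2.19) were higher, and both are combined rows, whose detection p is not a rank of their signal. PDZK1 and RARA (1.52) belong to the oestrogen-response list, OAS3 (1.29) to the interferon list and ID1 (1.29) to the TGF-beta targets, so these members are missing from the counts above.

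With 6 cultures there are 10 divisions into 3 and 3, too few for a share under 0.05, and the real division was the only 1 of 10 to reach its counts. It called 1518 rows higher and 1586 lower, and the highest count of any other was 0. The real division put 15 lists past the threshold, and the highest other was 11. As the other divisions mix the treatments unequally, the treatment difference both remains in them and widens their spread. Their counts do not measure what chance alone would give.

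The vehicle 3 repeat array differed from the first array of its culture by an SD of 0.446 (log2), against 0.278 for the estradiol 1 pair, and 375 rows differed at least 2-fold against 37. That array had the lowest mean signal (369.3, others 403.2 to 479.9) and the fewest detected rows (10172), but weaker signal widens the spread of dim rows most, and its SD was 2.17 times that of the estradiol pair over the brightest 20% of rows against 1.30 times over the dimmest 20%. A chip difference would recur in the estradiol pair, which also spans the chips, but the chip A minus chip B differences of both pairs were nearly uncorrelated across rows (r = 0.0144). Loss of short transcripts from that RNA sample is a candidate explanation for part of the difference: over 105 small RNA rows, leaving out SNORD3D and TERC, which had prompted the idea, the median difference was -0.261, below the lowest 5% of 1000 random draws (-0.029). Weaker signal for the dim rows (brightest over dimmest SD 1.06, or 0.643 with the offset subtracted), a mislabelled vehicle sample and real change between RNA samples stay open, the array correlating with vehicle 1 and 2 at 0.985 and 0.987, and no biological explanation was tested.

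ESR2 fell with estradiol although the doxycycline dose was the same. The 200 tested rows nearest in mean level had a median change of -0.0256, and 2 of the 200 fell by as much. Quantile normalization itself keeps such a median small, so this value cannot decide whether the normalization shifted rows of that brightness. With each array centred on its median in place of quantile normalization, ESR2 was still lower, at a log2 change of -1.01. A chip difference would end the call within a chip, but ESR2 was also lower within chip B alone (2 vehicle and 3 estradiol arrays, adjusted p = 0.000782, limma) and with the chip as a block (adjusted p = 1.05e-06), the value within chip A (0.00139) resting on 1 estradiol array assumed to vary like the others. An effect of estradiol on the transcript or on the inducible promoter stays open and was not tested; it would take a measurement known to separate the introduced gene from the cell's own.

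Genes next to each other in the genome changed together more often than random orders gave. Among 9401 pairs of neighbouring tested genes on GRCh38.p14, 496 were called in the same direction and 362 in opposite directions, against a median of 392 and a highest of 449 same-direction pairs in 1000 random orders. Paralogs account for part of this, as in the runs CST3, CST4, CST1, CST2 and CST5, or KRT13, KRT15, KRT19, KRT16 and KRT17, or SAA4, SAA2 and SAA1. Without pairs that share the first 3 letters of their symbols, 439 same-direction pairs remained, against a median of 376 and a highest of 434, so paralogs with alike names may not be the whole source. Regulation shared between neighbours is a hypothesis that this would fit, and paralogs with unlike names, transcripts that overlap and shared promoters stay open.

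A rise of an interferon transcript was tested as a possible source of the rise of interferon-stimulated genes. None of 22 interferon rows was detected on any array, so 0 could be called higher, and an amount below detection stays open.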
